A study of Danio rerio with 12 samples.

How the data were processed

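RNA was measured by poly(A)-selected sequencing of zebrafish larvae at 3 days after fertilization in 12 libraries, 3 for each of 4 groups made by genotype (wild type or gcn2-deficient) and oxygen (normoxia or hypoxia for 8 hours). The groups were taken from the sample titles. Per the labels, fastp, HISAT2 2.2.1 and featureCounts 2.0.6 were used with the GRCz11 assembly. The deposited table gives FPKM for 35004 genes in each library, with gene length in bases and gene start and end coordinates, and how the authors scaled the FPKM is not stated. FPKM multiplied by gene length came in whole steps in each library (checked within 0.05 of a step for 100% of the values), and these steps were used to recover reads. The table has 2484 genes with no symbol and 3602 at 0 in every library.

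Recovered reads per library were 16841145, 15945365 and 16634586 in wild-type normoxia, 16354653, 16524789 and 16282449 in knockout normoxia, 16578953, 16565980 and 16129265 in wild-type hypoxia, and 16651244, 16006110 and 15668848 in knockout hypoxia. No per-sample column was left without a sample. These depths set the counting error of low genes, and the spread between replicates enters the tests through the fit.

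The tests, the gene lists, the rule for named genes and most alternatives were set before the data were examined. Genes with FPKM of at least 1 in at least 3 of the 12 libraries were kept (21480 genes). Values were transformed as log2(FPKM + 1), and limma 3.58.1 in R 4.3.3 was fitted to all 12 libraries at once, with a mean for each group and a trend of variance with level. The 4 pairwise contrasts and the interaction of genotype and oxygen were each adjusted by Benjamini-Hochberg, with a threshold of 0.05. The replicate number was not a term. Over 18 pairs of libraries with the same number, the correlation of residuals ran from -0.087 to 0.119 with a median of 0.015, and 1 pair was above 0.1, so the numbers were not taken as pairs. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and figures.

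There were 37 gene lists, covering hypoxia and stress pathways, metabolism, blood and markers of other larval tissues. Some genes belong to several lists, so the lists are not independent. Lists were tested with limma's camera at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, which asks whether a list moves 1 way and compares it with no other genes. Benjamini-Hochberg was applied over the 37 lists, and the members of each list were also adjusted over the list alone.

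Named genes were chosen by rule: eif2ak4, the 8 largest rises and 8 largest falls with a mean of at least 2 FPKM in the higher group and libraries that did not overlap between groups, up to 3 members with the smallest p from each list past the camera test and from 6 lists of main interest, and 8 genes named in advance. For the interaction, the 10 genes with the smallest adjusted p were taken. Clone names and identifiers were left out. The rule was meant to give about 30 genes for a comparison and gave 85, 90, 75 and 91, so after the values were seen it was reduced to 1 member for each list outside those 6, which left 53, 53, 51 and 56.

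The tests were run on simulated data with the depths of the libraries and a single dispersion (0.00397). In the 4 contrasts and the interaction, 6%, 3.9%, 5.1%, 2.3% and 3.3% of the calls were false. Of 50 genes shifted by 0.5, the fits recovered 54%, 56%, 42%, 58% and 16%, and of those shifted by 1, 94%, 96%, 98%, 94% and 88%. These rates come from 153 to 184 calls per comparison and equal spread in all groups, unlike the data. They may not hold for the real fits. The fit had been run once on the deposited values before this test and was not altered. A first simulation, at a single depth, gave too many false calls in one contrast and was replaced.

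Alternatives were a pseudocount of 0.1, no filter, a filter at FPKM of at least 5, TPM scaling, median ratio scaling, quantile normalization, array weights, the replicate number as a block, the compared groups alone in the fit, a minimum absolute log2 fold change of 1, and each library left out in turn. Voom on the recovered reads and the ribosomal list without a kinase gene that its name pattern took in were added after the data were seen. The negative binomial tests planned for a table of raw counts were not run, since the table holds FPKM.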

Results

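Polyadenylated RNA was sequenced from zebrafish larvae at 3 days after fertilization, wild type or deficient in gcn2, that spent 8 hours in normoxia or hypoxia. Gcn2, encoded by eif2ak4, is a kinase that phosphorylates the translation factor eIF2 when amino acids run short. Each of the 4 groups held 3 libraries, stated by the labels to be biological replicates. Between 27371 and 27656 genes were above 0 in a library. Higher and lower between genotypes refer to the knockout. Fold changes are differences of group means on the log2(FPKM + 1) scale, which understates the fold of genes with low values, and errors after them are standard errors from limma. Adjusted p values are from limma (Benjamini-Hochberg) over 21480 genes, and group levels are mean FPKM ± SD with n = 3.

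The transcript of eif2ak4 (ENSDARG00000104276, GRCz11 scaffold KN150326.1, 26197 to 105474) was lower in every gcn2-deficient library than in every wild-type library. In wild-type larvae it measured 3.82, 3.91 and 3.63 FPKM in normoxia and 4.24, 4.18 and 4.25 FPKM in hypoxia. In gcn2-deficient larvae it measured 1.66, 1.85 and 1.70 FPKM in normoxia and 1.55, 1.95 and 1.52 FPKM in hypoxia. The group means were 3.79 ± 0.141 and 1.74 ± 0.104 FPKM in normoxia (log2 fold change -0.81 ± 0.08, adjusted p = 3.17e-05) and 4.22 ± 0.0365 and 1.67 ± 0.239 FPKM in hypoxia (log2 fold change -0.97 ± 0.08, adjusted p = 4.11e-06). Hypoxia itself gave log2 fold changes of 0.13 ± 0.08 in wild type (adjusted p = 0.24) and -0.04 ± 0.08 in the knockout (adjusted p = 0.739), neither past the test. The knockout value turned to 0.00 when knockout hypoxia replicate 3 was left out.

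In a principal component analysis, the first component held 42.6% of the variance and the second 26.9%, and the first ordered the groups without overlap. Wild-type normoxia libraries lay between -31.62 and -30.17 on it and knockout normoxia libraries between -19.52 and -17.64. Wild-type hypoxia libraries lay between 9.58 and 15.46 and knockout hypoxia libraries between 34.78 and 38.90. The share of reads on the mitochondrial genome was 3.48% to 3.67% in wild-type normoxia, 3.97% to 4.18% in knockout normoxia, 3.00% to 3.08% in wild-type hypoxia and 3.65% to 3.75% in knockout hypoxia. The 3 wild-type hypoxia libraries varied more among themselves than those of any other group, with a variance of 6.61 to 7.36 times that of counting error per pair of libraries, against 2.37 to 4.46 in the other groups.

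**Figure D1:**
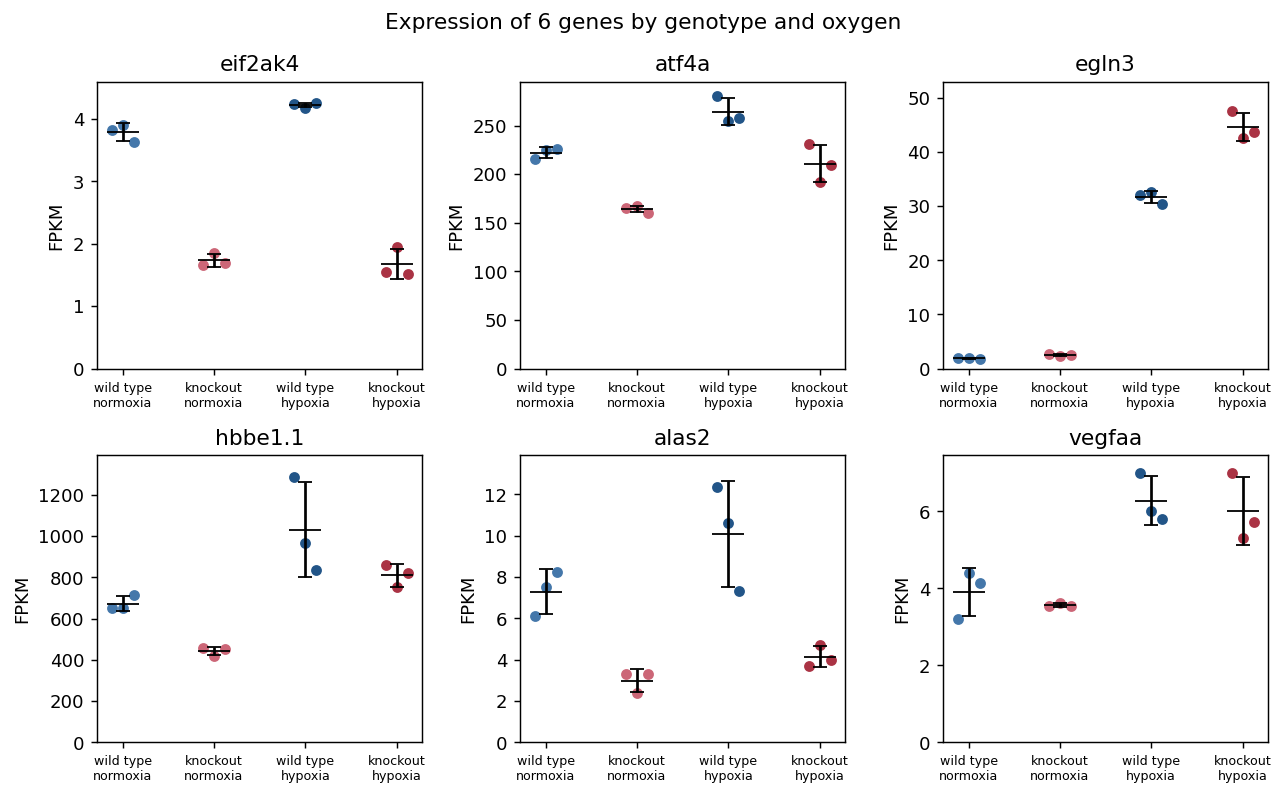
FPKM of eif2ak4, atf4a, egln3, hbbe1.1, alas2 and vegfaa in each of the 12 libraries, with points for libraries, a bar for the mean and whiskers for the SD (n = 3). All gcn2-deficient libraries sit at or below 1.95 FPKM for eif2ak4 and all wild-type libraries at or above 3.63 FPKM.

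Hypoxia against normoxia in wild type addressed how these larvae respond to 8 hours of low oxygen. The oxygen sensor egln3 (chromosome 17, 9912036 to 9936915), a prolyl hydroxylase that marks HIF for destruction, rose from 1.91 ± 0.0599 to 31.6 ± 1.16 FPKM (n = 3), a log2 fold change of 3.49 ± 0.06 with limma adjusted p = 7.22e-12. The embryonic globin hbae5 rose from 0.597 ± 0.190 to 20.2 ± 4.08 FPKM, and the sliding clamp of DNA replication, pcna, fell from 199 ± 13.8 to 70.6 ± 2.28 FPKM. Glucokinase, gck, which traps glucose in liver cells, fell from 8.22 ± 1.21 to 0.189 ± 0.0240 FPKM. In all, 7723 of 21480 genes changed (36%), 3598 higher and 4125 lower in hypoxia, and 366 of them by at least 1 on the log2 scale.

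Large rises beside egln3 were 3.72 ± 0.17 for hbae5, 3.64 ± 0.07 for ponzr4, 3.52 ± 0.16 for ponzr3 and 3.52 ± 0.11 for ankrd37, then 3.44 ± 0.15 for rhcga, 3.29 ± 0.15 for map1lc3cl and 2.93 ± 0.11 for cox4i1l, the last a subunit gene of cytochrome c oxidase. Beside gck (-2.95 ± 0.12), large falls were in pancreatic protease genes, at log2 fold changes of -2.13 ± 0.25 for ela3l, -2.13 ± 0.25 for prss59.1, -1.92 ± 0.29 for ela2 and -1.61 ± 0.27 for ctrb.3. Falls of similar size occurred in hmgcra (-1.67 ± 0.12), which encodes the rate-limiting enzyme of cholesterol synthesis, and in the cone photoreceptor genes opn1mw1 (-1.63 ± 0.18) and gngt2b (-1.59 ± 0.09).

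Among 63 HIF and hypoxia response genes, 45 rose and 1 fell, or 47 and 1 adjusted over the list alone (median log2 change 0.57, camera adjusted p = 1.92e-19, adjusted p = 0.0132 with an estimated correlation). Beside egln3, pfkfb3, an activator of glycolysis, rose by 2.22 ± 0.09 on the log2 scale and vegfaa, the angiogenic growth factor, from 3.92 ± 0.623 to 6.28 ± 0.639 FPKM (log2 fold change 0.57 ± 0.11, adjusted p = 0.00134). Erythropoietin, epoa, lay below the filter and was not tested, at 0.22, 0.28 and 0.22 FPKM in normoxia and 0.82, 1.02 and 0.65 FPKM in hypoxia. Of 34 glycolysis enzymes, 23 rose and 5 fell, or 24 and 5 adjusted over the list alone (median log2 change 0.37, camera adjusted p = 5.7e-08, adjusted p = 0.28 with an estimated correlation). The enolase and phosphoglycerate kinase genes had log2 fold changes of 1.00 ± 0.04 for eno1a and 0.87 ± 0.05 for pgk1. Among 40 autophagy and lysosome genes, 14 rose and 2 fell, or 16 and 2 adjusted over the list alone (median log2 change 0.10, camera adjusted p = 0.00296, adjusted p = 0.297 with an estimated correlation). The mitophagy receptor gene bnip3lb rose by 1.38 ± 0.07.

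Of 43 integrated stress response genes, 19 rose and 6 fell, or 20 and 6 adjusted over the list alone (median log2 change 0.18, camera adjusted p = 0.000891, adjusted p = 0.297 with an estimated correlation). Log2 fold changes were 2.46 ± 0.11 for ddit4, 1.72 ± 0.09 for ppp1r15a and 0.59 ± 0.05 for slc7a3a, where ddit4 restrains mTORC1, ppp1r15a directs the eIF2 phosphatase and slc7a3a carries cationic amino acids. The transcription factor gene atf4a rose by 0.25 ± 0.06 (adjusted p = 0.00785), from 222 ± 5.69 to 264 ± 14.3 FPKM. Among 20 cytosolic aminoacyl-tRNA synthetases, 11 fell and 2 rose, also adjusted over the list alone (median log2 change -0.25, camera adjusted p = 0.0106, adjusted p = 0.311 with an estimated correlation). The glutaminyl-tRNA synthetase gene qars1 fell, at -0.71 ± 0.06. Of 14 eIF2 factors and kinases without eif2ak4, 6 fell and 2 rose, or 6 and 3 adjusted over the list alone (median log2 change -0.06, camera adjusted p = 0.464).

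Among 11 globins, 8 rose and 0 fell, also adjusted over the list alone (median log2 change 0.68, camera adjusted p = 3.32e-05, adjusted p = 0.297 with an estimated correlation). Globin log2 fold changes were 1.69 ± 0.05 for hbbe2, 0.67 ± 0.12 for hbae3 and 0.59 ± 0.12 for hbbe1.1. The globin hbae1.1 rose by 0.78 ± 0.27 (adjusted p = 0.0384), but the call was lost without any 1 wild-type normoxia library or wild-type hypoxia replicate 1 or 2 (adjusted p up to 0.109), with no filter (0.0795), with array weights (0.0549) and with the replicate block (0.0566). Of 40 erythroid genes, 12 rose and 5 fell, also adjusted over the list alone (median log2 change 0.15, camera adjusted p = 0.0544). The erythroid list passed with quantile normalization (0.0478) and without wild-type normoxia replicate 2 (0.0478) or 3 (0.0452) or wild-type hypoxia replicate 3 (0.0326). The red cell anion exchanger gene slc4a1a rose by 1.94 ± 0.07, nt5c2l1 by 1.33 ± 0.11 and the membrane skeleton gene epb41b by 0.85 ± 0.10. The erythroid enzyme of haem synthesis, alas2, had a log2 fold change of 0.40 ± 0.16 that did not pass (adjusted p = 0.0716), and it passed without wild-type hypoxia replicate 3 (0.60, adjusted p = 0.00646) and with voom (adjusted p = 0.0174). The erythroid transcription factor gene gata1a was at -0.28 ± 0.16 (adjusted p = 0.193). Among 26 genes of the haem biosynthesis list, 10 fell and 4 rose, or 10 and 5 adjusted over the list alone (median log2 change -0.12, camera adjusted p = 0.129). Within that list alad and hmbsa fell (-0.63 ± 0.07 and -0.56 ± 0.10) and hmox1a, which breaks haem down, rose (0.47 ± 0.08).

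Of 52 proliferation genes, 51 fell and 0 rose, also adjusted over the list alone (median log2 change -0.80, camera adjusted p = 2.23e-28, adjusted p = 0.0319 with an estimated correlation). Among 30 cholesterol and fatty acid synthesis genes, 23 fell and 2 rose, or 24 and 2 adjusted over the list alone (median log2 change -0.59, camera adjusted p = 1.32e-10, adjusted p = 0.00826 with an estimated correlation). The gene insig1, which restrains sterol synthesis, rose within that list (1.36 ± 0.09). Of 82 nuclear genes of oxidative phosphorylation, 54 fell and 3 rose, or 60 and 3 adjusted over the list alone (median log2 change -0.26, camera adjusted p = 2.16e-11, adjusted p = 0.312 with an estimated correlation). One member, cox6b1, rose by 0.85 ± 0.07. Among 13 mitochondrial genome genes, 8 fell and 0 rose, also adjusted over the list alone (median log2 change -0.41, camera adjusted p = 7.05e-05, adjusted p = 0.297 with an estimated correlation). Among these, MT-ATP6 fell, at -0.84 ± 0.06. Of 31 ER chaperone and unfolded protein response genes, 21 fell and 1 rose, also adjusted over the list alone (median log2 change -0.27, camera adjusted p = 1.1e-06, adjusted p = 0.0236 with an estimated correlation). The chaperone gene hspa5 fell, at -0.51 ± 0.04. Among 29 heat shock genes, 15 fell and 4 rose, or 16 and 4 adjusted over the list alone (median log2 change -0.23, camera adjusted p = 0.000891, adjusted p = 0.297 with an estimated correlation). The mitochondrial chaperone gene hspd1 fell, at -1.02 ± 0.04. Of 29 Nrf2 oxidative stress genes, 15 fell and 4 rose, also adjusted over the list alone (median log2 change -0.27, camera adjusted p = 0.000258, adjusted p = 0.29 with an estimated correlation). The thioredoxin reductase gene txnrd3 fell, at -0.64 ± 0.06.

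Among 16 exocrine pancreas markers, 12 fell and 0 rose, or 13 and 0 adjusted over the list alone (median log2 change -1.03, camera adjusted p = 6.83e-06, adjusted p = 0.311 with an estimated correlation). Of 15 intestine markers, 9 fell and 2 rose, or 10 and 2 adjusted over the list alone (median log2 change -0.43, camera adjusted p = 0.0199, adjusted p = 0.444 with an estimated correlation). Its call was lost without wild-type normoxia replicate 1 (adjusted p = 0.0549) or wild-type hypoxia replicate 2 (adjusted p = 0.0654), and the gluconeogenesis gene pck1 rose within it (2.37 ± 0.07). Among 23 photoreceptor markers, 14 fell and 0 rose, or 15 and 0 adjusted over the list alone (median log2 change -0.69, camera adjusted p = 5.93e-07, adjusted p = 0.297 with an estimated correlation). The cone kinase gene grk7a fell, at -1.21 ± 0.10. Of 27 skeletal muscle markers, 15 rose and 0 fell, or 16 and 0 adjusted over the list alone (median log2 change 0.22, camera adjusted p = 4.14e-06, adjusted p = 0.297 with an estimated correlation). Among 11 cardiac muscle markers, 7 rose and 0 fell, also adjusted over the list alone (median log2 change 0.38, camera adjusted p = 0.000319, adjusted p = 0.149 with an estimated correlation). The actin gene acta1a rose by 0.84 ± 0.07 and the natriuretic peptide gene nppa by 1.25 ± 0.12. Of 21 epidermis markers, 13 rose and 6 fell, or 14 and 6 adjusted over the list alone (median log2 change 0.31, camera adjusted p = 0.0115, adjusted p = 0.461 with an estimated correlation). Among 20 endothelial markers, 7 rose and 0 fell, also adjusted over the list alone (median log2 change 0.18, camera adjusted p = 0.00623, adjusted p = 0.0862 with an estimated correlation). The keratin gene krt8 rose by 0.69 ± 0.06 and the apelin gene apln by 0.29 ± 0.05.

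Of 76 ribosomal proteins, 11 rose and 0 fell, or 3 and 0 adjusted over the list alone (median log2 change 0.09, camera adjusted p = 0.0173, adjusted p = 0.762 with an estimated correlation). That call was lost with quantile normalization (adjusted p = 0.262), without wild-type normoxia replicate 2 (0.0594) and without wild-type hypoxia replicate 1 (0.867). The list was taken by a name pattern that also took in a kinase gene, rps6kal (0.47 ± 0.07), and 10 of the other 75 members rose.

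Hypoxia against normoxia in gcn2-deficient larvae addressed the same response in the other genotype. The oxygen sensor egln3 rose from 2.47 ± 0.230 to 44.5 ± 2.62 FPKM (n = 3), a log2 fold change of 3.71 ± 0.06 with limma adjusted p = 1.88e-12. The p53 target pmaip1, which encodes the cell death activator Noxa, rose from 3.99 ± 0.593 to 44.7 ± 8.68 FPKM, and haem oxygenase, hmox1a, from 8.44 ± 0.306 to 30.3 ± 2.71 FPKM. The apolipoprotein B gene apoba fell (-1.84 ± 0.10). A total of 9451 genes changed (44%), 4684 higher and 4767 lower, 545 of them by at least 1 on the log2 scale. With TPM scaling, which moved the median log2 fold change of all genes to -0.12, the split was 2787 higher and 7239 lower.

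Large rises beside egln3 were 4.20 ± 0.07 for ponzr4, 4.13 ± 0.15 for rhcga and 4.00 ± 0.11 for ankrd37, with ponzr3 from 7.60 ± 0.491 to 148 ± 21.4 FPKM, then 3.67 ± 0.15 for map1lc3cl, 3.48 ± 0.23 for pdk2b and 3.18 ± 0.14 for pmaip1, where pdk2b encodes a kinase that closes the pyruvate dehydrogenase step. Large falls were in pancreatic protease genes, at -2.15 ± 0.25 for ela3l, -1.99 ± 0.25 for prss59.1, -1.98 ± 0.29 for ela2 and -1.85 ± 0.27 for ctrb.3. Further falls were -1.87 ± 0.14 for guca1g, -1.85 ± 0.45 for pclaf and -1.63 ± 0.15 for cyp2aa9.

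Among 63 HIF and hypoxia response genes, 46 rose and 4 fell, or 47 and 4 over the list alone (median log2 change 0.78, camera adjusted p = 5.17e-19, adjusted p = 0.0185 with an estimated correlation). The mitophagy receptor gene bnip3lb rose by 1.90 ± 0.07 and vegfaa by 0.61 ± 0.11, from 3.57 ± 0.0484 to 6.02 ± 0.881 FPKM. Erythropoietin, epoa, again lay below the filter, at 0.31, 0.35 and 0.39 FPKM in normoxia and 0.77, 0.56 and 1.19 FPKM in hypoxia. Of 34 glycolysis enzymes, 24 rose and 2 fell, or 24 and 3 over the list alone (median log2 change 0.62, camera adjusted p = 2.13e-10, adjusted p = 0.127 with an estimated correlation). The glycolytic log2 fold changes were 1.22 ± 0.04 for eno1a, 1.03 ± 0.05 for gapdhs and 1.01 ± 0.05 for pgk1. Among 40 autophagy and lysosome genes, 23 rose and 2 fell, or 24 and 2 over the list alone (median log2 change 0.30, camera adjusted p = 3.13e-07, adjusted p = 0.0831 with an estimated correlation). Of 43 integrated stress response genes, 23 rose and 8 fell, or 23 and 9 over the list alone (median log2 change 0.29, camera adjusted p = 0.000602, adjusted p = 0.179 with an estimated correlation). The log2 fold changes were 2.96 ± 0.11 for ddit4, 2.21 ± 0.09 for ppp1r15a and 1.26 ± 0.07 for pck2. The gene atf4a rose by 0.36 ± 0.06 (adjusted p = 0.000613), from 164 ± 3.58 to 211 ± 19.2 FPKM, but did not pass with quantile normalization (adjusted p = 0.0711). Among 20 cytosolic aminoacyl-tRNA synthetases, 14 fell and 2 rose, also over the list alone (median log2 change -0.29, camera adjusted p = 0.000849, adjusted p = 0.191 with an estimated correlation). The valyl-tRNA synthetase gene vars1 fell, at -0.68 ± 0.06. Of 14 eIF2 factors and kinases without eif2ak4, 4 fell and 3 rose, also over the list alone (median log2 change -0.07, camera adjusted p = 0.595).

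Among 11 globins, 8 rose and 0 fell, also over the list alone (median log2 change 0.87, camera adjusted p = 0.000114, adjusted p = 0.291 with an estimated correlation). The log2 fold changes were 1.33 ± 0.05 for hbbe2, 2.56 ± 0.17 for hbae5 and 0.87 ± 0.12 for hbbe1.1. The globin hbae1.1 was at 0.72 ± 0.27 (adjusted p = 0.045), a call lost under many alternatives, up to an adjusted p of 0.201 without knockout hypoxia replicate 1, and its libraries overlapped between the groups. Of 40 erythroid genes, 15 rose and 4 fell, also over the list alone (median log2 change 0.19, camera adjusted p = 0.0142, adjusted p = 0.146 with an estimated correlation). The anion exchanger gene slc4a1a rose by 1.15 ± 0.07, the mitochondrial glycine carrier gene slc25a38a by 1.39 ± 0.14 and the water channel gene aqp1a.1 by 0.52 ± 0.06. Among 26 genes of the haem biosynthesis list, 8 rose and 7 fell, also over the list alone (median log2 change 0.07, camera adjusted p = 0.357). Within it hmox1a rose by 1.73 ± 0.08 and clpxa, a mitochondrial unfoldase gene, by 0.74 ± 0.06. The gene alas2 was at 0.37 ± 0.16 (adjusted p = 0.0823), and passed without wild-type hypoxia replicate 3 (adjusted p = 0.0295), with array weights (0.0453) and with the compared groups alone in the fit (0.0384). The gene gata1a was at 0.05 ± 0.16 (adjusted p = 0.827), and turned negative with TPM scaling (-0.04).

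Of 52 proliferation genes, 52 fell and 0 rose, also over the list alone (median log2 change -0.83, camera adjusted p = 2.23e-26, adjusted p = 0.0523 with an estimated correlation). Among 30 cholesterol and fatty acid synthesis genes, 23 fell and 3 rose, also over the list alone (median log2 change -0.74, camera adjusted p = 4.05e-07, adjusted p = 0.0185 with an estimated correlation). The gene insig1 rose by 1.93 ± 0.09 and pcna fell, at -1.52 ± 0.06. Of 82 nuclear genes of oxidative phosphorylation, 14 rose and 7 fell, or 7 and 2 over the list alone (median log2 change 0.04, camera adjusted p = 0.449). With TPM scaling and quantile normalization that list passed as lower (adjusted p = 0.0475 and 3.9e-05). Among 13 mitochondrial genome genes, 8 fell and 2 rose, also over the list alone (median log2 change -0.32, camera adjusted p = 0.00507, adjusted p = 0.361 with an estimated correlation). The mitochondrial gene MT-ND1 fell, at -0.62 ± 0.05. Of 76 ribosomal proteins, 60 rose and 0 fell, or 61 and 0 over the list alone (median log2 change 0.31, camera adjusted p = 6.09e-12, adjusted p = 0.353 with an estimated correlation). The kinase gene rps6kal rose by 0.52 ± 0.07, and 59 of the other 75 members rose. Among 31 ER chaperone and unfolded protein response genes, 16 fell and 2 rose, or 17 and 2 over the list alone (median log2 change -0.21, camera adjusted p = 0.000398, adjusted p = 0.0831 with an estimated correlation). The chaperone gene hspa5 fell, at -0.68 ± 0.04. Of 27 p53 target genes, 13 rose and 3 fell, or 14 and 4 over the list alone (median log2 change 0.17, camera adjusted p = 0.00507, adjusted p = 0.0992 with an estimated correlation).

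Among 31 inflammation and acute phase genes, 22 rose and 1 fell, also over the list alone (median log2 change 0.43, camera adjusted p = 8.47e-06, adjusted p = 0.0992 with an estimated correlation). The cyclooxygenase gene ptgs2a rose by 1.01 ± 0.09. Of 31 circadian clock genes, 14 rose and 1 fell, or 14 and 2 over the list alone (median log2 change 0.18, camera adjusted p = 0.00954, adjusted p = 0.291 with an estimated correlation). The clock output gene tefa rose by 0.70 ± 0.07. Among 17 macrophage markers, 6 rose and 1 fell, also over the list alone (median log2 change 0.27, camera adjusted p = 0.0435, adjusted p = 0.144 with an estimated correlation). The receptor gene csf1ra rose by 0.89 ± 0.07, and the list's call was lost without knockout normoxia replicate 2 (0.0569), wild-type hypoxia replicate 1 (0.0524) or knockout hypoxia replicate 1 (0.0551). Of 20 endothelial markers, 9 rose and 0 fell, also over the list alone (median log2 change 0.18, camera adjusted p = 0.0132, adjusted p = 0.0992 with an estimated correlation). The tight junction gene cldn5b rose by 0.68 ± 0.08. Among 16 exocrine pancreas markers, 11 fell and 0 rose, or 12 and 0 over the list alone (median log2 change -1.01, camera adjusted p = 4.51e-05, adjusted p = 0.304 with an estimated correlation). The amylase gene amy2a fell, at -1.41 ± 0.13.

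Of 27 skeletal muscle markers, 26 rose and 0 fell, also over the list alone (median log2 change 0.37, camera adjusted p = 9.35e-11, adjusted p = 0.144 with an estimated correlation). Among 11 cardiac muscle markers, 7 rose and 0 fell, also over the list alone (median log2 change 0.34, camera adjusted p = 0.00181, adjusted p = 0.144 with an estimated correlation). The genes acta1a and nppa rose by 1.04 ± 0.07 and 1.21 ± 0.12. Of 29 lens crystallins, 20 rose and 2 fell, also over the list alone (median log2 change 0.25, camera adjusted p = 0.000398, adjusted p = 0.292 with an estimated correlation). The crystallin gene cryba2b rose by 0.38 ± 0.05, and the list did not pass with quantile normalization (adjusted p = 0.397). Among 21 epidermis markers, 14 rose and 2 fell, also over the list alone (median log2 change 0.43, camera adjusted p = 0.000137, adjusted p = 0.292 with an estimated correlation). The keratin gene krt8 rose by 0.88 ± 0.06. Of 16 ionocyte markers, 8 rose and 3 fell, or 10 and 3 over the list alone (median log2 change 0.15, camera adjusted p = 0.0173, adjusted p = 0.334 with an estimated correlation). That call was also lost with quantile normalization (0.121). Among 20 cartilage and bone markers, 8 fell and 3 rose, also over the list alone (median log2 change -0.17, camera adjusted p = 0.0182, adjusted p = 0.334 with an estimated correlation). The collagen gene col11a1a fell from 143 ± 3.54 to 83.7 ± 8.01 FPKM.

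Both genotypes shared much of the hypoxia response. Across 21480 genes, 2363 rose in both and 2620 fell in both, against 785 and 915 if the calls were independent, and 155 were called in opposite directions. The 2 sets of log2 fold changes came from separate libraries and had a Pearson correlation of 0.695 and a Spearman correlation of 0.61 across genes, which are not independent replicates.

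Gcn2-deficient against wild-type larvae in normoxia addressed how the genotypes, and perhaps stocks, differ at ordinary oxygen. The galectin gene lgals3b (chromosome 17, 10824659 to 10838434) fell from 57.2 ± 4.34 to 0.467 ± 0.141 FPKM (n = 3), a log2 fold change of -5.31 ± 0.11 with limma adjusted p = 1.16e-11. The haem-binding plasma protein gene hpxa rose from 0.571 ± 0.101 to 9.68 ± 0.304 FPKM. The erythroid enzyme of haem synthesis, alas2 (chromosome 8, 21353878 to 21369028), fell from 7.28 ± 1.08 to 2.99 ± 0.534 FPKM (log2 fold change -1.05 ± 0.16, adjusted p = 0.000993), and the globin hbbe2 from 150.0 ± 3.16 to 82.7 ± 3.12 FPKM. Altogether 3595 genes changed (16.7%), 1638 higher and 1957 lower in the knockout, 263 of them by at least 1 on the log2 scale. The count was 2048 without wild-type normoxia replicate 3, 2266 and 2144 without knockout normoxia replicates 2 and 3, and 5471 with array weights, and TPM scaling split it into 2145 higher and 1252 lower.

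Beside hpxa (2.77 ± 0.12), large rises were in the pancreatic protease genes, at 2.21 ± 0.41 for ctrb.2, 2.11 ± 0.15 for cela1.7 and 1.98 ± 0.25 for ela3l, followed by 1.97 ± 0.11 for ms4a17a.8, 1.94 ± 0.11 for capn2l, 1.90 ± 0.17 for tep1 and 1.89 ± 0.11 for mbl2, of which mbl2 encodes a lectin of the complement system. The gene malb (chromosome 17, 22102791 to 22106541) measured 27.0 ± 1.69 FPKM in wild type and was listed at 0 in the 3 knockout libraries, so no fold is given. Other falls were -2.01 ± 0.16 for taco1, -1.83 ± 0.16 for gsta.2 and -1.64 ± 0.12 for gck, where taco1 activates translation of a cytochrome c oxidase subunit and gsta.2 is a glutathione transferase gene, and -1.59 ± 0.06 for spock2, -1.58 ± 0.16 for ccdc34 and -1.52 ± 0.11 for p2rx7, of which p2rx7 encodes an ATP-gated channel.

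Of 11 globins, 6 were lower and 0 higher, also over the list alone (median log2 change -0.63, camera adjusted p = 0.000733, adjusted p = 0.574 with an estimated correlation). The log2 fold changes were -0.85 ± 0.05 for hbbe2, -0.81 ± 0.13 for hbae1.3, -0.63 ± 0.12 for hbae3 and -0.60 ± 0.12 for hbbe1.1, and hbae1.1 was at -0.21 ± 0.27 (adjusted p = 0.623), positive without knockout normoxia replicate 1 (0.03). Among 40 erythroid genes, 7 were lower and 4 higher, or 9 and 5 over the list alone (median log2 change -0.07, camera adjusted p = 0.241). Beside alas2, the synuclein gene sncga and the blood transcription factor gene tal1 fell (-0.67 ± 0.12 and -0.43 ± 0.08). The gene gata1a measured 1.08 ± 0.223 FPKM in wild type and 1.08 ± 0.339 in the knockout (adjusted p = 0.993). Of 26 genes of the haem biosynthesis list, 1 were higher and 1 lower, also over the list alone (median log2 change 0.02, camera adjusted p = 0.542). The porphyrin transporter gene abcb6a rose by 0.37 ± 0.09 (adjusted p = 0.0136), a call lost without wild-type normoxia replicate 1 (0.0578) or knockout normoxia replicate 2 (0.0526).

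Among 43 integrated stress response genes, 8 were lower and 5 higher, or 9 and 6 over the list alone (median log2 change -0.04, camera adjusted p = 0.624). The gene atf4a fell from 222 ± 5.69 to 164 ± 3.58 FPKM (log2 fold change -0.43 ± 0.06, adjusted p = 0.000653), while the amino acid transporter genes slc38a3a and slc7a3a rose (0.58 ± 0.07 and 0.32 ± 0.05). Of 20 cytosolic aminoacyl-tRNA synthetases, 7 were lower and 0 higher, or 10 and 0 over the list alone (median log2 change -0.16, camera adjusted p = 0.00701, adjusted p = 0.497 with an estimated correlation). That call was lost with quantile normalization (0.0677). The threonyl-tRNA synthetase gene tars1 fell (-0.22 ± 0.05, adjusted p = 0.0134), and the call was lost without wild-type normoxia replicate 3 (0.0569) or knockout normoxia replicate 3 (0.0537). Among 14 eIF2 factors and kinases without eif2ak4, 0 were higher and 0 lower, also over the list alone (median log2 change -0.05, camera adjusted p = 0.718). Of 63 HIF and hypoxia response genes, 10 were higher and 1 lower, also over the list alone (median log2 change 0.04, camera adjusted p = 0.134). Members igfbp1a and igfbp1b rose (0.88 ± 0.12 and 0.75 ± 0.11) and the oxidase gene ero1a fell (-0.54 ± 0.11). The sensor egln3 rose by 0.25 ± 0.06 (adjusted p = 0.0194), a call lost without wild-type normoxia replicate 3 (0.0718), without knockout normoxia replicate 1 (0.0764) or 3 (0.0547), with voom (0.102) and with the compared groups alone in the fit (0.0673). The gene vegfaa was at -0.10 ± 0.11 (adjusted p = 0.571). Among 34 glycolysis enzymes, 9 were higher and 8 lower, or 10 and 8 over the list alone (median log2 change 0.04, camera adjusted p = 0.542). The phosphofructokinase gene pfkpb rose by 0.58 ± 0.07 and gck and gpib fell (-1.64 ± 0.12 and -0.55 ± 0.08).

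Of 16 exocrine pancreas markers, 10 were higher and 1 lower, or 13 and 2 over the list alone (median log2 change 0.80, camera adjusted p = 1.22e-06, adjusted p = 0.48 with an estimated correlation). Among 15 intestine markers, 9 were higher and 2 lower, or 9 and 3 over the list alone (median log2 change 0.70, camera adjusted p = 5.86e-05, adjusted p = 0.369 with an estimated correlation). Of 23 hepatocyte markers, 8 were higher and 3 lower, also over the list alone (median log2 change 0.06, camera adjusted p = 0.0279, adjusted p = 0.716 with an estimated correlation). The hepatocyte call was lost without wild-type normoxia replicate 2 (adjusted p = 0.464). The amylase gene amy2a rose by 1.24 ± 0.13, pck1 by 0.81 ± 0.07 and the liver fatty acid carrier gene fabp10a by 0.82 ± 0.07. Among 27 skeletal muscle markers, 20 were lower and 1 higher, or 22 and 1 over the list alone (median log2 change -0.26, camera adjusted p = 9.58e-10, adjusted p = 0.369 with an estimated correlation). The actin gene acta1a fell, at -0.99 ± 0.07. Of 25 neuron markers, 9 were higher and 0 lower, or 13 and 0 over the list alone (median log2 change 0.22, camera adjusted p = 0.000181, adjusted p = 0.574 with an estimated correlation). The enzyme gene of GABA synthesis, gad2, rose by 0.45 ± 0.08. Among 29 lens crystallins, 14 were lower and 0 higher, or 19 and 0 over the list alone (median log2 change -0.20, camera adjusted p = 9.37e-08, adjusted p = 0.369 with an estimated correlation). The crystallin gene crybb1l3 fell, at -0.79 ± 0.08. Of 31 circadian clock genes, 11 were higher and 0 lower, or 12 and 1 over the list alone (median log2 change 0.19, camera adjusted p = 0.000337, adjusted p = 0.369 with an estimated correlation). The clock repressor gene nr1d1 rose from 1.67 ± 0.174 to 7.55 ± 1.17 FPKM.

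Among 52 proliferation genes, 20 were lower and 1 higher, or 28 and 1 over the list alone (median log2 change -0.23, camera adjusted p = 4.01e-08, adjusted p = 0.369 with an estimated correlation). The spindle gene nusap1 fell, at -0.49 ± 0.08. Of 30 cholesterol and fatty acid synthesis genes, 15 were lower and 1 higher, or 17 and 1 over the list alone (median log2 change -0.34, camera adjusted p = 3.39e-06, adjusted p = 0.0548 with an estimated correlation). The sterol demethylation gene msmo1 fell, at -0.94 ± 0.09. Among 31 ER chaperone and unfolded protein response genes, 10 were lower and 1 higher, or 15 and 1 over the list alone (median log2 change -0.12, camera adjusted p = 0.000258, adjusted p = 0.151 with an estimated correlation). The chaperone gene calr fell, at -0.51 ± 0.07. Of 29 heat shock genes, 5 were lower and 0 higher, also over the list alone (median log2 change -0.12, camera adjusted p = 0.000999, adjusted p = 0.48 with an estimated correlation). The collagen chaperone gene serpinh1b fell, at -0.80 ± 0.08. Among 13 mitochondrial genome genes, 1 were higher and 0 lower, or 4 and 0 over the list alone (median log2 change 0.15, camera adjusted p = 0.00408, adjusted p = 0.612 with an estimated correlation). The gene MT-CYB rose by 0.22 ± 0.06 (adjusted p = 0.022), a call lost without wild-type normoxia replicate 2 (0.079) or 3 (0.071), without knockout normoxia replicate 1 (0.0778) or 3 (0.094) and with no filter (0.0894). Of 76 ribosomal proteins, 2 were lower and 0 higher, or 0 and 0 over the list alone (median log2 change -0.11, camera adjusted p = 0.000124, adjusted p = 0.716 with an estimated correlation). That call was lost with quantile normalization (0.899), and that of rps27.1 (-0.27 ± 0.07, adjusted p = 0.0203) without wild-type normoxia replicate 1 (0.0639) or 3 (0.0939) or knockout normoxia replicate 1 (0.0579) or 2 (0.0736). Of the 15 lists called with the preset correlation, 0 kept the call with an estimated correlation, 3 of 37 had an unadjusted p under 0.05, and fry called 14.

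Gcn2-deficient against wild-type larvae in hypoxia addressed how the genotypes differ once oxygen is low. The p53 target pmaip1 was higher in the knockout, at 44.7 ± 8.68 against 3.84 ± 0.442 FPKM (n = 3, log2 fold change 3.22 ± 0.14, limma adjusted p = 2.01e-08). The liver enzyme gene tat, which degrades tyrosine, was at 45.7 ± 7.24 against 3.91 ± 0.859 FPKM, and hmox1a at 30.3 ± 2.71 against 10.9 ± 0.924 FPKM. The globin hbbe2 was lower, at 209.9 ± 7.53 against 486 ± 26.0 FPKM, as was alas2, at 4.14 ± 0.510 against 10.1 ± 2.56 FPKM. In total 7111 genes differed (33.1%), 3641 higher and 3470 lower in the knockout, 478 of them by at least 1 on the log2 scale, and with TPM scaling the split was 2826 higher and 4246 lower.

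Other large rises were 2.86 ± 0.12 for hpxa, 2.43 ± 0.11 for ms4a17a.8 and 2.27 ± 0.18 for apoa4b.3, then 1.96 ± 0.25 for ela3l, 1.95 ± 0.15 for cela1.7 and 1.94 ± 0.20 for slc15a1b, where apoa4b.3 is an apolipoprotein gene and slc15a1b carries peptides in the gut. Large falls were lgals3b, from 68.7 ± 8.07 to 0.547 ± 0.175 FPKM (-5.49 ± 0.11), and malb, from 19.6 ± 2.34 to 0.0478 ± 0.0828 FPKM. Other falls were -2.08 ± 0.16 for gsta.2, -1.77 ± 0.17 for qpct, -1.57 ± 0.16 for ccdc34 and -1.54 ± 0.06 for spock2. The channel gene p2rx7 fell from 3.19 ± 0.649 to 0.216 ± 0.0507 FPKM and the transporter gene slc16a6a from 2.04 ± 0.394 to 0.0117 ± 0.0101 FPKM.

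Among 11 globins, 5 were lower and 0 higher, or 7 and 0 over the list alone (median log2 change -0.60, camera adjusted p = 0.00102, adjusted p = 0.384 with an estimated correlation). The log2 fold changes were -1.21 ± 0.05 for hbbe2, -0.83 ± 0.12 for hbae3 and -1.09 ± 0.17 for hbae5. The globin hbbe1.1 was at -0.32 ± 0.12 (adjusted p = 0.0526), and passed as lower with TPM scaling (0.0079), quantile normalization (0.00238), voom (0.0108), the replicate block (0.0426) and a filter at 5 FPKM (0.0393), and without wild-type hypoxia replicate 3 (0.00516). The globin hbae1.1 was at -0.27 ± 0.27 (adjusted p = 0.473) and gata1a at 0.32 ± 0.16 (adjusted p = 0.136). Of 40 erythroid genes, 10 were lower and 8 higher, also over the list alone (median log2 change 0.02, camera adjusted p = 0.726). Members bpgm and rhag rose (0.59 ± 0.08 and 0.53 ± 0.07) while alas2 and epb41b fell (-1.09 ± 0.16 and -0.73 ± 0.10), where bpgm sets the oxygen affinity of haemoglobin and rhag is a red cell membrane transporter gene. Among 26 genes of the haem biosynthesis list, 15 were higher and 1 lower, also over the list alone (median log2 change 0.32, camera adjusted p = 0.000231, adjusted p = 0.147 with an estimated correlation). Within it hmox1a, clpxa and clpxb rose (1.39 ± 0.08, 0.53 ± 0.06 and 0.57 ± 0.06).

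Of 63 HIF and hypoxia response genes, 33 were higher and 6 lower, or 35 and 6 over the list alone (median log2 change 0.23, camera adjusted p = 1.72e-05, adjusted p = 0.147 with an estimated correlation). Among its members, the log2 fold changes were 1.12 ± 0.08 for pdk2a, 1.40 ± 0.11 for igfbp1b, 1.04 ± 0.09 for ndrg1b and 0.48 ± 0.06 for egln3, and vegfaa was at -0.06 ± 0.11 (adjusted p = 0.731), with a value of 0.01 or 0.02 without wild-type hypoxia replicate 1 or knockout hypoxia replicate 2. Among 34 glycolysis enzymes, 21 were higher and 6 lower, or 21 and 7 over the list alone (median log2 change 0.22, camera adjusted p = 0.000348, adjusted p = 0.364 with an estimated correlation). The glycolytic genes ldhbb, pgam1b and pfkpb rose (1.01 ± 0.09, 0.50 ± 0.05 and 0.56 ± 0.07). Of 43 integrated stress response genes, 15 were higher and 13 lower, or 18 and 15 over the list alone (median log2 change 0.10, camera adjusted p = 0.364). The enzyme gene pck2 and the autophagy adaptor gene sqstm1 rose (0.87 ± 0.07 and 0.60 ± 0.06), the neutral amino acid transporter gene slc1a4 fell (-0.80 ± 0.08) and atf4a fell (-0.33 ± 0.06, adjusted p = 0.00189). Among 20 cytosolic aminoacyl-tRNA synthetases, 11 were lower and 1 higher, or 12 and 1 over the list alone (median log2 change -0.18, camera adjusted p = 0.00122, adjusted p = 0.269 with an estimated correlation). The alanyl-tRNA synthetase gene aars1 fell, at -0.42 ± 0.05. Of 14 eIF2 factors and kinases without eif2ak4, 2 were higher and 1 lower, also over the list alone (median log2 change -0.003, camera adjusted p = 0.971).

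Among 82 nuclear genes of oxidative phosphorylation, 61 were higher and 0 lower, or 72 and 0 over the list alone (median log2 change 0.25, camera adjusted p = 2.07e-15, adjusted p = 0.291 with an estimated correlation). The complex I gene ndufs6 rose from 35.6 ± 1.67 to 53.9 ± 5.29 FPKM. Of 13 mitochondrial genome genes, 6 were higher and 0 lower, or 7 and 0 over the list alone (median log2 change 0.17, camera adjusted p = 0.000662, adjusted p = 0.364 with an estimated correlation). The gene MT-CO2 rose by 0.39 ± 0.06. Among 29 Nrf2 oxidative stress genes, 13 were higher and 2 lower, or 17 and 3 over the list alone (median log2 change 0.24, camera adjusted p = 1.81e-05, adjusted p = 0.147 with an estimated correlation). Of 27 p53 target genes, 10 were higher and 1 lower, or 11 and 1 over the list alone (median log2 change 0.15, camera adjusted p = 0.00102, adjusted p = 0.147 with an estimated correlation). Among 31 inflammation and acute phase genes, 19 were higher and 0 lower, also over the list alone (median log2 change 0.40, camera adjusted p = 2.08e-06, adjusted p = 0.147 with an estimated correlation). The iron hormone gene hamp rose by 1.37 ± 0.17. Of 40 autophagy and lysosome genes, 22 were higher and 3 lower, or 23 and 3 over the list alone (median log2 change 0.23, camera adjusted p = 1.72e-05, adjusted p = 0.147 with an estimated correlation). The autophagy gene wipi2 rose by 0.60 ± 0.05. Among 31 circadian clock genes, 18 were higher and 1 lower, also over the list alone (median log2 change 0.35, camera adjusted p = 2.5e-05, adjusted p = 0.147 with an estimated correlation). The cryptochrome gene cry1a rose by 0.87 ± 0.08.

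Of 52 proliferation genes, 32 were lower and 0 higher, also over the list alone (median log2 change -0.30, camera adjusted p = 1.73e-09, adjusted p = 0.162 with an estimated correlation). The thymidine kinase gene tk1 fell, at -0.62 ± 0.08. Among 30 cholesterol and fatty acid synthesis genes, 11 were lower and 4 higher, or 14 and 4 over the list alone (median log2 change -0.21, camera adjusted p = 0.00911, adjusted p = 0.147 with an estimated correlation). The sterol demethylase gene cyp51 fell, at -0.92 ± 0.10. Of 20 cartilage and bone markers, 16 were lower and 0 higher, also over the list alone (median log2 change -0.37, camera adjusted p = 1.59e-07, adjusted p = 0.147 with an estimated correlation). The cartilage collagen gene col11a1a fell from 140.5 ± 10.9 to 83.7 ± 8.01 FPKM. Among 76 ribosomal proteins, 5 were higher and 0 lower, or 0 and 0 over the list alone (median log2 change 0.12, camera adjusted p = 0.00114, adjusted p = 0.684 with an estimated correlation). That call was lost without wild-type hypoxia replicate 3 (0.278) or knockout hypoxia replicate 1 (0.101). The call of rpl11 (0.23 ± 0.07, adjusted p = 0.0181) was lost without wild-type hypoxia replicate 2 (0.0642) or 3 (0.0561) or knockout hypoxia replicate 1 (0.0728) and with the compared groups alone in the fit (0.0893), and its libraries overlapped between the groups.

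Of 23 photoreceptor markers, 16 were higher and 1 lower, or 17 and 1 over the list alone (median log2 change 0.59, camera adjusted p = 8.15e-06, adjusted p = 0.364 with an estimated correlation). The cone opsin gene opn1mw2 rose by 0.85 ± 0.07. Among 16 ionocyte markers, 10 were higher and 0 lower, or 12 and 0 over the list alone (median log2 change 0.33, camera adjusted p = 5.01e-05, adjusted p = 0.165 with an estimated correlation). The ammonia transporter gene rhcgb rose by 1.19 ± 0.11. Of 16 exocrine pancreas markers, 11 were higher and 1 lower, or 12 and 1 over the list alone (median log2 change 0.81, camera adjusted p = 6.16e-05, adjusted p = 0.376 with an estimated correlation). Among 15 intestine markers, 11 were higher and 1 lower, or 12 and 1 over the list alone (median log2 change 0.72, camera adjusted p = 2.5e-06, adjusted p = 0.157 with an estimated correlation). The apolipoprotein gene apoa4b.2 rose by 1.90 ± 0.14. Of 23 hepatocyte markers, 11 were higher and 2 lower, or 11 and 3 over the list alone (median log2 change 0.09, camera adjusted p = 0.00467, adjusted p = 0.474 with an estimated correlation). Among 27 skeletal muscle markers, 9 were lower and 3 higher, also over the list alone (median log2 change -0.11, camera adjusted p = 0.0492, adjusted p = 0.649 with an estimated correlation). The muscle parvalbumin gene pvalb4 rose by 0.71 ± 0.05, and the list's call was lost without any 1 of 9 libraries, reaching an adjusted p = 0.194 without knockout hypoxia replicate 3. Of the 22 lists called in this comparison, 0 kept the call with an estimated correlation, 11 of 37 had an unadjusted p under 0.05, and fry called 26.

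The genotype difference was partly shared between oxygen levels. Of 21480 genes, 1042 were higher and 1057 lower in the knockout in both normoxia and hypoxia, against 278 and 316 if the calls were independent, and 91 were called in opposite directions. Across genes, which are not independent replicates, the Pearson correlation of the log2 fold changes was 0.593 and the Spearman correlation 0.382.

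**Figure D2:**
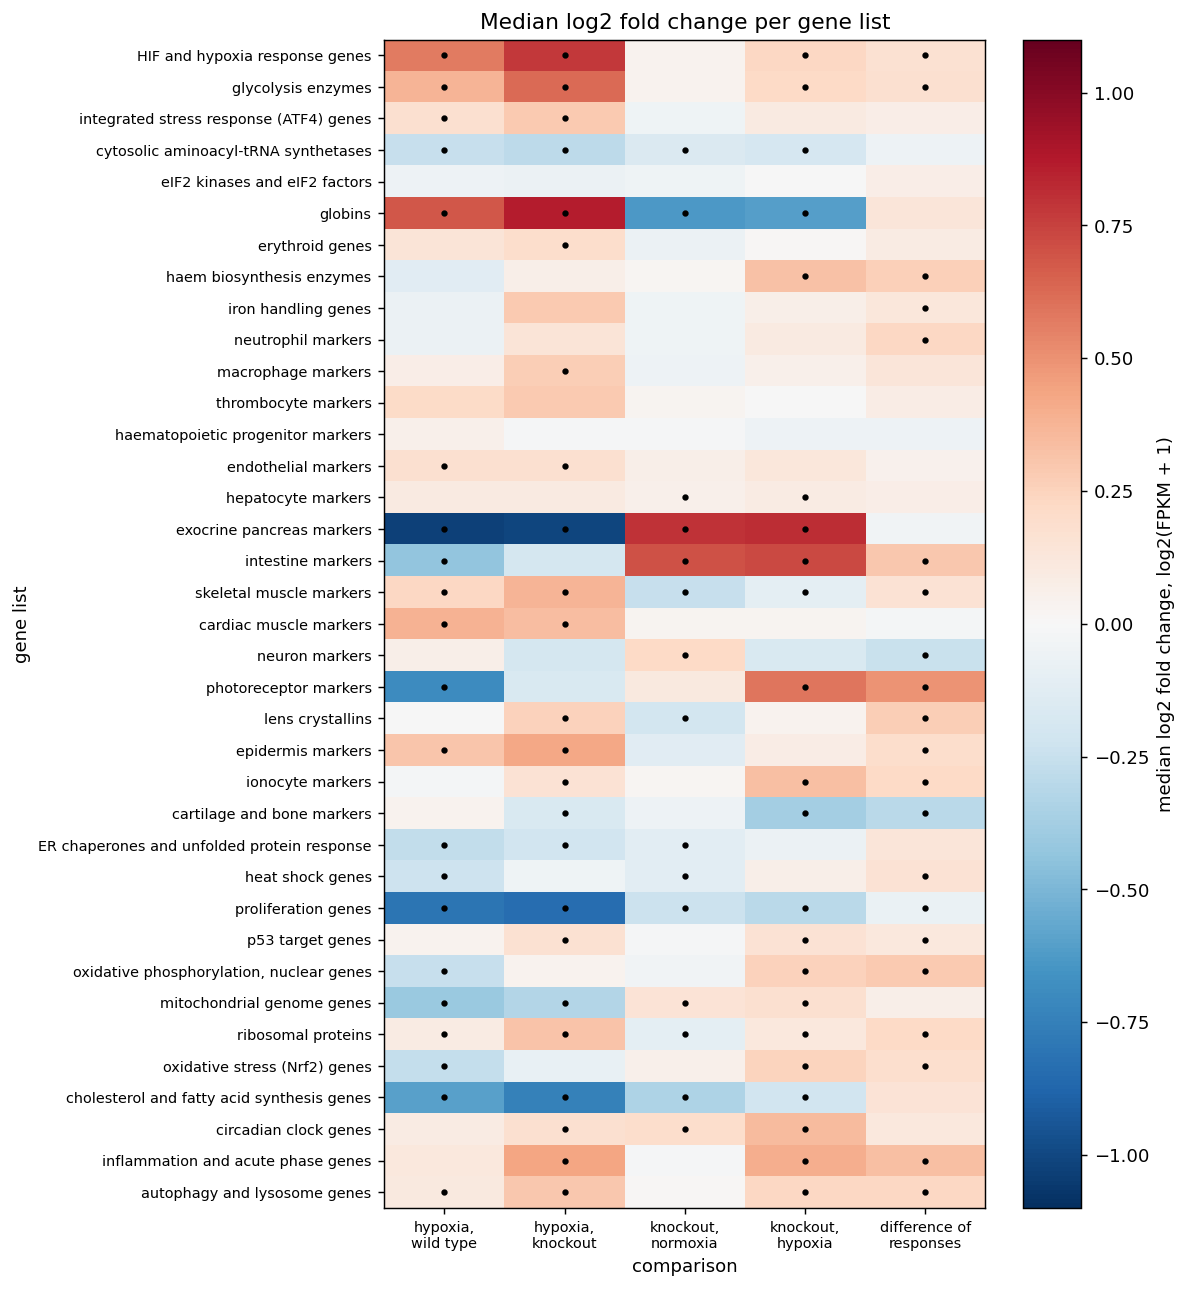
Median log2 fold change on the log2(FPKM + 1) scale of each of 37 gene lists in the 4 pairwise comparisons and in the difference of the hypoxia responses, with a dot where the camera adjusted p is under 0.05. The HIF list has a median of 0.57 in wild type and 0.78 in the knockout under hypoxia, and the globins a median of -0.63 between genotypes in normoxia.

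The interaction of genotype and oxygen addressed whether gcn2-deficient larvae respond to hypoxia otherwise than wild type. The gene pmaip1 rose in the knockout, as above, and went from 2.61 ± 0.362 to 3.84 ± 0.442 FPKM (n = 3) in wild type, a difference between the responses of 2.76 ± 0.19 on the log2 scale (limma adjusted p = 8.63e-05). For hmox1a, with 7.58 ± 0.653 and 10.9 ± 0.924 FPKM in wild type, the difference was 1.25 ± 0.11 (adjusted p = 0.000452). The chaperone genes hsp70.1 and hsp90aa1.2 also responded higher in the knockout (differences of 1.60 ± 0.17 and 0.97 ± 0.09). Responses differed in 1986 of 21480 genes (9.2%), 1019 with a higher and 967 with a lower response in the knockout, and in 89 by at least 1 on the log2 scale.

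The pentose phosphate enzyme gene pgd went in wild type from 40.2 ± 2.75 to 25.6 ± 1.59 FPKM and stood at 36.2 ± 1.82 and 47.9 ± 4.36 FPKM in the knockout (difference 1.02 ± 0.11). The purine synthesis gene gart went from 14.6 ± 0.752 to 12.4 ± 0.761 FPKM in wild type and from 14.8 ± 0.591 to 6.32 ± 0.200 FPKM in the knockout (difference -0.89 ± 0.09). The actin gene ACTC1 went from 89.3 ± 4.61 to 173 ± 13.9 FPKM in wild type and from 68.9 ± 3.04 to 77.8 ± 1.18 FPKM in the knockout (difference -0.77 ± 0.09). The mitochondrial adenylate kinase gene ak3 and bzw1b had differences of 0.89 ± 0.09 and 1.26 ± 0.13. Glucokinase, gck, had a difference of 1.60 ± 0.17, with the knockout starting from 1.96 ± 0.391 FPKM and both genotypes ending at or below 0.19 FPKM. With voom it did not pass (adjusted p = 0.0507).

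Of 1986 genes, 423 with a higher and 569 with a lower knockout response were called by hypoxia in the knockout and not in wild type, and 204 and 202 in wild type and not in the knockout. Another 68 and 87 were called in opposite directions. The absolute response was larger in the knockout in 1378 genes (69.4%). The count depended on single libraries and settings. It was 480 and 655 without wild-type normoxia replicates 1 and 3, 1040, 1085 and 557 without knockout normoxia replicates 1, 2 and 3, 997 without wild-type hypoxia replicate 2, and 611 and 1242 without knockout hypoxia replicates 1 and 2. With no filter it was 1230 and with voom 3000, and TPM scaling gave 429 higher and 1720 lower, quantile normalization 658 and 1066.

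Of 82 nuclear genes of oxidative phosphorylation, 26 had a higher and 0 a lower response, or 60 and 0 over the list alone (median log2 difference 0.29, camera adjusted p = 3.02e-18, adjusted p = 0.273 with an estimated correlation). Among 63 HIF and hypoxia response genes, 9 had a higher and 3 a lower response, or 15 and 3 over the list alone (median log2 difference 0.17, camera adjusted p = 0.000771, adjusted p = 0.273 with an estimated correlation). Of 34 glycolysis enzymes, 5 had a higher and 0 a lower response, or 7 and 1 over the list alone (median log2 difference 0.17, camera adjusted p = 0.000109, adjusted p = 0.322 with an estimated correlation). The glycolysis call was lost with quantile normalization (0.64). Among 26 haem biosynthesis enzymes, 7 had a higher and 0 a lower response, or 9 and 1 over the list alone (median log2 difference 0.27, camera adjusted p = 0.000215, adjusted p = 0.21 with an estimated correlation). Of 23 iron handling genes, 4 had a higher and 0 a lower response, also over the list alone (median log2 difference 0.12, camera adjusted p = 0.0219, adjusted p = 0.21 with an estimated correlation). That call was lost with quantile normalization (0.171). Among 29 Nrf2 oxidative stress genes, 5 had a higher and 0 a lower response, or 6 and 0 over the list alone (median log2 difference 0.18, camera adjusted p = 0.000211, adjusted p = 0.273 with an estimated correlation). Of 27 p53 target genes, 5 had a higher and 0 a lower response, or 6 and 0 over the list alone (median log2 difference 0.12, camera adjusted p = 0.00454, adjusted p = 0.21 with an estimated correlation). Among 29 heat shock genes, 8 had a higher and 0 a lower response, or 9 and 0 over the list alone (median log2 difference 0.15, camera adjusted p = 0.000211, adjusted p = 0.273 with an estimated correlation). Of 31 inflammation and acute phase genes, 6 had a higher and 0 a lower response, or 7 and 0 over the list alone (median log2 difference 0.33, camera adjusted p = 6.04e-05, adjusted p = 0.21 with an estimated correlation). Among 40 autophagy and lysosome genes, 13 had a higher and 0 a lower response, or 14 and 0 over the list alone (median log2 difference 0.23, camera adjusted p = 2.94e-05, adjusted p = 0.21 with an estimated correlation).

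Of 43 integrated stress response genes, 8 had a higher and 3 a lower response, or 9 and 5 over the list alone (median log2 difference 0.08, camera adjusted p = 0.22). Among 20 cytosolic aminoacyl-tRNA synthetases, 0 had a higher and 2 a lower response, also over the list alone (median log2 difference -0.06, camera adjusted p = 0.143). It passed as lower with TPM scaling (0.00756) and quantile normalization (0.00279). Of 14 eIF2 factors and kinases without eif2ak4, 0 had a higher and 1 a lower response, also over the list alone (median log2 difference 0.07, camera adjusted p = 0.739). Among 11 globins, 0 had a higher and 2 a lower response, also over the list alone (median log2 difference 0.13, camera adjusted p = 0.452). The globin list passed as lower without wild-type hypoxia replicate 3 (adjusted p = 0.0281), and its mean log2 difference was negative while its median was positive. Of 40 erythroid genes, 2 had a higher and 3 a lower response, or 7 and 4 over the list alone (median log2 difference 0.09, camera adjusted p = 0.518). The differences for the single genes hbbe2, hbae5 and slc4a1a were -0.35, -1.16 and -0.79 on the log2 scale (adjusted p = 0.0179, 0.0181 and 0.00348). For alas2, atf4a, egln3 and vegfaa the differences were -0.03, 0.11, 0.23 and 0.04, none past the test (adjusted p = 0.949, 0.477, 0.128 and 0.892).

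Among 25 neuron markers, 0 had a higher and 11 a lower response, or 1 and 12 over the list alone (median log2 difference -0.24, camera adjusted p = 7.54e-05, adjusted p = 0.339 with an estimated correlation). Of 20 cartilage and bone markers, 0 had a higher and 7 a lower response, or 0 and 10 over the list alone (median log2 difference -0.30, camera adjusted p = 4.3e-06, adjusted p = 0.21 with an estimated correlation). Among 52 proliferation genes, 0 had a higher and 2 a lower response, or 0 and 0 over the list alone (median log2 difference -0.07, camera adjusted p = 0.0355, adjusted p = 0.565 with an estimated correlation). The proliferation call was lost without 6 single libraries, among them wild-type hypoxia replicate 1 (adjusted p = 0.289). Of 23 photoreceptor markers, 3 had a higher and 0 a lower response, or 14 and 1 over the list alone (median log2 difference 0.50, camera adjusted p = 2.44e-05, adjusted p = 0.346 with an estimated correlation). Among 29 lens crystallins, 7 had a higher and 0 a lower response, or 18 and 1 over the list alone (median log2 difference 0.27, camera adjusted p = 7.78e-06, adjusted p = 0.273 with an estimated correlation). Of 16 ionocyte markers, 1 had a higher and 0 a lower response, or 6 and 0 over the list alone (median log2 difference 0.22, camera adjusted p = 0.000139, adjusted p = 0.273 with an estimated correlation). Among 76 ribosomal proteins, 1 had a higher and 0 a lower response, or 0 and 0 over the list alone (median log2 difference 0.22, camera adjusted p = 2.36e-09, adjusted p = 0.487 with an estimated correlation). The lens call was lost with quantile normalization (0.21).

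Of 27 skeletal muscle markers, 2 had a higher and 0 a lower response, or 3 and 0 over the list alone (median log2 difference 0.16, camera adjusted p = 7.54e-05, adjusted p = 0.346 with an estimated correlation). Among 21 epidermis markers, 2 had a higher and 0 a lower response, or 3 and 0 over the list alone (median log2 difference 0.19, camera adjusted p = 0.00294, adjusted p = 0.487 with an estimated correlation). Of 15 intestine markers, 4 had a higher and 0 a lower response, or 4 and 1 over the list alone (median log2 difference 0.29, camera adjusted p = 0.0301, adjusted p = 0.487 with an estimated correlation). Among 15 neutrophil markers, 1 had a higher and 0 a lower response, also over the list alone (median log2 difference 0.23, camera adjusted p = 0.0252, adjusted p = 0.282 with an estimated correlation). Quantile normalization ended the calls of skeletal muscle (0.8), epidermis (0.824) and intestine (0.0997), and leaving out wild-type hypoxia replicate 2 or knockout hypoxia replicate 2 ended that of the neutrophil list (0.0725 and 0.059). The intestine call was also lost without wild-type normoxia replicate 1 (0.0834), knockout normoxia replicate 1 (0.0961), wild-type hypoxia replicate 2 (0.0945) or knockout hypoxia replicate 2 (0.0767). Of the 21 lists called for the difference in response, 0 kept the call with an estimated correlation, 6 of 37 had an unadjusted p under 0.05, and fry called 17.

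**Figure D3:**
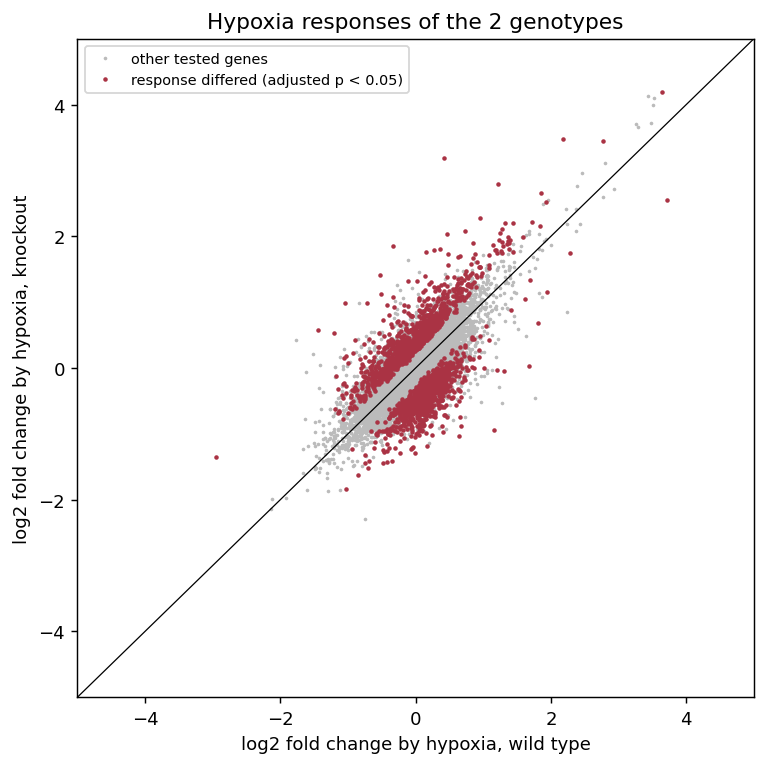
Log2 fold change by hypoxia in wild type (horizontal axis) and in gcn2-deficient larvae (vertical axis), 1 point per gene on the log2(FPKM + 1) scale, with genes whose responses differed in red and the line of equal responses in black. The correlation across 21480 genes is 0.695, and 1986 genes are in red.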

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

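The results here had a hypoxia response that differed by the interaction test. Among the tests weighed, the test of scaling by TPM and quantile values was chosen after the result was seen, and the rule for neighbouring genes was made stricter after its result was seen. Genes were placed by the deposited coordinates after a first placement from a reference table had covered too few of them.

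Responses to hypoxia differed in 1986 genes, with the larger absolute response in the knockout in 69.4%. Median ratio scaling left 69.4%, but it changed every library by the same factor (1.0068). The deposited values thus already had equal median ratios, and this rescaling decides nothing. TPM scaling gave 75.3% of 2149 genes, but it moved the median hypoxia change of all genes by more in the knockout, to -0.12, than in wild type (-0.02), and decides nothing either. Quantile normalization gave 70.5% of 1724, which argues against the authors' scaling as the whole cause. Of 100 splits of the genotype labels within each oxygen level, 3 gave at least 1986 genes, the real one included, a share under the 0.05 set in advance. The others were 7029, from the split that swapped the genotypes in normoxia, and 2041, from one that mixed them there. The 12 splits with the true hypoxia labels gave at least 185 genes and the rest at most 5. The counts thus follow the genotype difference in hypoxia, a structure of the samples, and (judged afterwards) do not decide whether chance can be excluded. Without single libraries the share ran from 64.6% to 75.2%, a check added afterwards. Whether the larger response in the knockout is biological stays open, since stocks may differ and no scaling was shown to be the right one.

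In the 4 pairwise comparisons the 6 libraries allow 10 splits, too few for a share under 0.05. In each of them 1 split of 10 gave as many genes, the real one. The real counts and the highest other counts were 7723 and 0 for hypoxia in wild type, 9451 and 1 for hypoxia in the knockout, 3595 and 1 for genotype in normoxia, and 7111 and 1 for genotype in hypoxia.

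A second pattern was the 2099 genes that differed between genotypes in the same direction at both oxygen levels, led by lgals3b and malb on chromosome 17. A place for eif2ak4, which lies on an unplaced scaffold, came from its neighbours in a reference table, of which 7 of 10 are on chromosome 17. That chromosome holds 4.62% of the pattern's genes and 3.67% of all tested genes, which argues against linked variants on it as the whole cause, and among the 100 genes nearest to the neighbours 6% belong to the pattern (95% exact interval 2.2% to 12.6%) against 9.8% elsewhere, a ratio of 0.61 (Fisher's exact p = 0.239, two-sided). Between chromosomes the share in the pattern ran from 6.1% of tested genes on chromosome 9 to 13.2% on 15 and 15.6% on 11, with 12.3% on 17. Neighbouring pairs numbered 353 against 201.4 in shuffled orders, a ratio of 1.75. That is 1.53 times the ratio of all 4983 genes changed alike by hypoxia in both genotypes (1.14), which met the rule set in advance, and above the highest of 100 random draws of 2099 of them (1.33). It is 1.28 times that of the 2099 with the smallest p (1.37), but without names of the same stem these ratios were 1.47, 1.14 and 1.38, short of the stricter rule, so stretches of the genome that differ between stocks remain a possible explanation. The labels do not say whether the knockout and wild-type larvae were siblings.

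The other genes are given as differences of log2 fold change, knockout minus wild type. Stress and cell death genes had pmaip1 at 2.76, hsp70.1 at 1.60, hmox1a at 1.25, hsp90aa1.2 at 0.97, ppp1r15a at 0.49 and pck2 at 0.51. Blood genes had hbae5 at -1.16, hbbe2 at -0.35, slc4a1a at -0.79, epb41b at -0.72, slc25a38a at 0.82 and clpxa at 0.41. Metabolic genes had gck at 1.60, pdk2b at 1.3, pgd at 1.02, ak3 at 0.89, gart at -0.89, insig1 at 0.57, apoba at -0.81 and cyp2aa9 at -0.77. The remaining genes were ponzr4 at 0.56, bnip3lb at 0.52, cryba2b at 0.31, col11a1a at -0.68, tefa at 0.58, ptgs2a at 0.68, bzw1b at 1.26 and ACTC1 at -0.77.

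Gene lists are given as the median of the same difference. Metabolic and stress lists were at 0.29 for nuclear oxidative phosphorylation genes, 0.17 for HIF and hypoxia response, 0.17 for glycolysis, 0.27 for the haem list, 0.12 for iron handling, 0.15 for heat shock, 0.12 for p53 targets, 0.18 for Nrf2, 0.33 for inflammation, 0.23 for autophagy, 0.22 for ribosomal proteins and -0.07 for proliferation. Tissue lists were at 0.23 for neutrophils, 0.29 for intestine, 0.16 for skeletal muscle, -0.24 for neurons, 0.50 for photoreceptors, 0.27 for lens, 0.19 for epidermis, 0.22 for ionocytes and -0.30 for cartilage and bone. With an estimated correlation 0 of these lists passed.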

How the results depend on the processing

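Voom and the ribosomal list without its kinase gene were chosen after the data were seen. Counts of changed genes stayed within 1.5 times the reported count under the alternatives run, except those given here. Hypoxia changed 6331 to 7781 genes in wild type and 7967 to 9662 in the knockout when single libraries were left out, and genotype 5224 to 6979 in hypoxia. For genotype in normoxia the range was 2048 to 3993, and array weights gave 5471, against 5857 for genotype in hypoxia. For the interaction the range was 480 to 2839, with 1230 with no filter, where more genes were tested, and 3000 with voom. The cause of these shifts was not tested.

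A minimum absolute log2 fold change of 1 left 366, 545, 263, 478 and 89 genes in the order of the report, by construction. With an estimated correlation 4, 2, 0, 0 and 0 gene lists passed, against 21, 24, 15, 22 and 21. With the replicate number as a block the gene counts were 7606, 9319, 3534, 6931 and 1979.

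Of 351 values for named genes, TPM scaling kept the call and direction of 345, quantile normalization of 342 and voom of 347. No called value changed sign. Uncalled values near 0 that did were gata1a with TPM scaling (-0.037 for hypoxia in the knockout, 0.033 for genotype in normoxia) and with array weights (0.031 for genotype in normoxia), and others with single libraries left out. Those ranged from -0.109 to 0.004 for eif2ak4 and -0.087 to 0.15 for gata1a (hypoxia in the knockout), from -0.486 to 0.03 for hbae1.1 and -0.105 to 0.132 for gata1a (genotype in normoxia), and from -0.155 to 0.017 for vegfaa (genotype in hypoxia). The cause was not tested. Median ratio scaling multiplied every library by 1.0068 and tests nothing. The interaction has no fit of the compared groups alone, and its smallest difference called in the data was 0.221.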
